A study of Homo sapiens with 44 samples.

How the data were processed

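RNA was measured in 44 VCaP xenograft tumors by sequencing of libraries made, per the labels' protocols, with the Illumina TruSeq RNA v2 kit, which does not mark strand. Per the labels, mice had been allocated to arms so as to balance PSA, its change, body weight, cage and the week of castration. The authors deposited 1 table of raw counts per gene, with 23368 gene symbols and 1 column per tumor. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Picard 1.77, HTSeq 0.6.1 and the hg19 build were used. Their order and parameters, the gene annotation, the strand setting and the treatment of mouse reads are not given in the sources used here. Reads of mouse cells in the tumors may therefore stand in the counts of human genes that they resemble. Genes with near-identical or closely related copies are uncertain (UGT2B15 and UGT2B17, AKR1C2 and AKR1C3, KLK2 and KLK3, ribosomal proteins and their pseudogenes). Overlapping and antisense genes are uncertain too, since reads could be split or shared between all such genes.

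Each column was matched to its tumor by the label in the sample record (0 columns unmatched), and arms and replicate numbers were taken from the sample titles. No 2 columns of an arm held the same values, and the lowest chi-square per degree of freedom between 2 libraries of an arm was 3.42, 4.61 and 3.92 for vehicle, enzalutamide and ARN-509, so every library was counted once. Of the genes, 2790 had 0 counts in all libraries. filterByExpr by arm kept 13517 genes. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a negative binomial quasi-likelihood model with robust estimation and arm as the only term, in 1 fit of all 44 libraries. The contrasts enzalutamide minus vehicle, ARN-509 minus vehicle and enzalutamide minus ARN-509 were tested with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Unless stated otherwise, adjusted p-values of genes are from this test. The SE of a log2 fold change is its absolute value divided by the square root of F, and 95% intervals use the t distribution with the total degrees of freedom of the test. Levels are CPM of the TMM-scaled total of the tested genes unless stated otherwise, as mean ± SD, and M before counts is the SI prefix mega.

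Lists of genes (25) were fixed together with the tests, the alternatives and the rule for named genes before the data were examined. Lists with at least 3 tested members (21) were tested with limma 3.58.1 camera on voom values with a preset inter-gene correlation of 0.01, and with an estimated correlation and fry beside it. Adjusted p-values of lists are over the 21. With the estimated correlation 0 lists passed in any of the 3 comparisons. The lists of drug metabolism and transport, macrophage and leukocyte, erythrocyte, and mitochondrially encoded genes had too few tested members and gave no result. Genes named are, for each drug, the 10 that rose and the 10 that fell most among those past the threshold with a mean log2 CPM of at least 1, the 10 smallest p between the drugs, 14 genes of androgen signalling and proliferation where tested, and up to 4 members of each list described with the smallest p. Members of a list beyond these 4 are named where they moved against its name or where the fallen members were the MCM genes, and were picked after their values were seen.

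The depth ran from 3377450 to 30.1 M counts per library, apart from enzalutamide 4 with 80142. On simulated counts with the real means and library sizes, with 100 of the 13517 genes changed 1.5-fold and 100 changed 2-fold, the test recovered 82% and 95% for enzalutamide against vehicle, 83% and 98% for ARN-509 against vehicle, and 82% and 99% between the drugs. False calls made up 4.84%, 7.65% and 5.24% of all calls. The list test recovered a list lowered 1.5-fold in each simulated comparison and called 1 other list, in enzalutamide against vehicle. Simulated genes were drawn independently, so false list calls where members vary together were not tested.

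Alternatives were DESeq2 size factors or library totals in place of TMM, no filter or a stricter one (at least 1 CPM in at least 14 libraries), no robust estimation, a replicate block, DESeq2 1.42.0, limma voom with quality weights, only the 2 arms compared, a 2-fold minimum and leaving out each library in turn. Added after the data were seen were the fits without enzalutamide 4, with each library's trend with GC content and transcript length removed (alone and without enzalutamide 4), and with 43 libraries thinned to 3377450 counts. GC content and length came from a GRCh38 annotation matched by symbol, which gave values for 88.9% of tested genes; no coordinates were used. On simulated counts with the same linear GC trend in every ARN-509 library, 5043 false calls became 0 after the removal. No true change and no length trend was simulated, so whether the removal keeps true differences was not tested. Relations between tumors within an arm and some genes and lists are not reported here. Unchanged arms, 20 pairs, were simulated from the mean of the same vehicle libraries, which understates the covariance that shared vehicle libraries cause.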

Results

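RNA sequencing was analysed from xenograft tumors of VCaP, an established human prostate cancer cell line that carries the TMPRSS2-ERG fusion. The tumors grew in athymic nude mice and had become castration-resistant, since treatment started only after serum PSA had regained its level from before castration. There were 44 libraries in 3 arms: 15 from mice given vehicle, 14 from mice given enzalutamide and 15 from mice given ARN-509. Each drug was given by gavage at 20 mg/kg/day for 4 weeks. Both drugs are antiandrogens. The number of libraries in each arm equals the number of mice treated, so each library was taken as 1 tumor of 1 mouse.

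The libraries held between 4.19 and 25.8 M counts in the vehicle arm (median 5.71), between 3.38 and 30.1 M in the ARN-509 arm (median 7.49) and, in 13 enzalutamide libraries, between 4.72 and 16.9 M (median 8.62). The remaining library, enzalutamide 4, held 80142 counts. Its log2 CPM had a Pearson r of 0.425 with the mean of the other enzalutamide libraries, across genes averaging at least 50 CPM. The next lowest values were 0.887 for vehicle 8 and 0.916 for vehicle 10, and each of the other libraries had at least 0.954 with its own arm. All 44 libraries entered the tests. Mean levels of the enzalutamide arm are given over the 13 other libraries, and fold changes come from the fit of all 44.

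**Figure D1:**
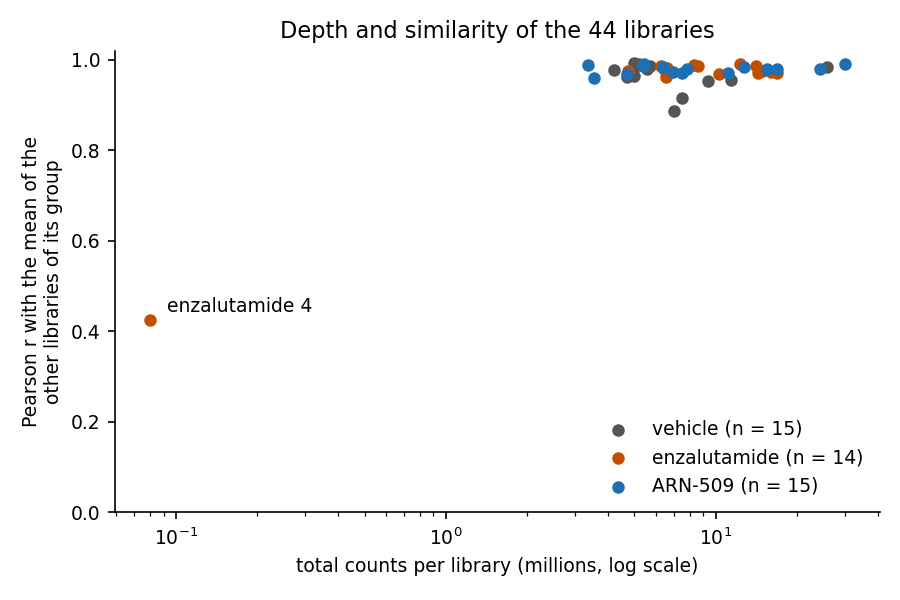
Total counts per library (M, log axis) against the Pearson r of each library's log2 CPM with the mean of the other libraries of its arm, for 15 vehicle, 14 enzalutamide and 15 ARN-509 libraries. Enzalutamide 4, with 80142 counts and an r of 0.425, stands apart from the other 43 points, which lie at 0.887 or above.

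The first comparison asked which transcripts differ between castration-resistant tumors treated with enzalutamide and with vehicle. Several genes that androgen induces fell. STEAP4, a metalloreductase, averaged 62.5 ± 41.3 CPM (SD, n = 15) in vehicle tumors and 3.37 ± 2.23 CPM (n = 13) in enzalutamide tumors, a log2 fold change of -4.22 ± 0.45 (SE, adjusted p = 5.61e-09). TRPM8, a cold-sensing cation channel, fell from 478 ± 202 to 82.1 ± 45.4 CPM (log2 -2.54 ± 0.28, adjusted p = 1.35e-08), and FKBP5, a co-chaperone of steroid receptors, fell by 0.46 ± 0.12 on the log2 scale (adjusted p = 0.00593). KLK3, which encodes PSA, averaged 332 ± 203 and 296 ± 164 CPM, and its log2 difference of -0.19 did not pass the test (95% interval -0.63 to 0.25, adjusted p = 0.673).

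Of 13517 genes tested, 613 rose and 641 fell under enzalutamide (9.28%), and 86 and 110 of these changed at least 2-fold. The genes that fell most were FAM189A2, STEAP4, DPP4, LUZP2, ST6GALNAC1, CACNG4, TESC, TRPM8, KRT14 and PIGR, with log2 values from -4.30 to -2.42. DPP4 is a cell surface dipeptidyl peptidase, ST6GALNAC1 a sialyltransferase and KRT14 a keratin of basal epithelium. PIGR, the polymeric immunoglobulin receptor, lost its call without vehicle 12 (adjusted p = 0.259). Among the 10 genes that rose most were NOV, a secreted matricellular protein, which went from 1.67 ± 1.10 to 12.6 ± 3.39 CPM (log2 2.89 ± 0.22, adjusted p = 2.36e-13), SLC7A14 at 2.94 ± 0.26, SAMD11 at 2.46 ± 0.25, LOC100130417 at 2.30 ± 0.24 and GRIA2, a glutamate receptor subunit, at 2.31 ± 0.34. ALB, the albumin gene, also stood among them at 3.33 ± 0.64, but its log2 value was 0.52 without enzalutamide 2. The other 4, MYL6, TPM1, DDX5 and CNBP, rose through enzalutamide 4. Without that library their log2 values were 0.11, 0.20, -0.012 and 0.053, with adjusted p from 0.0790 to 0.927, and 1455 genes passed the test in all.

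Among other genes chosen for their part in androgen signalling or growth, KLK2 (-0.06), TMPRSS2 (0.22), ERG (-0.18), the glucocorticoid receptor gene NR3C1 (0.44), the steroid-conjugating UGT2B15 (0.20) and UGT2B17 (0.01), AKR1C3 (0.26), and the proliferation markers MKI67 (-0.34) and TOP2A (-0.19) did not pass the test under enzalutamide. CYP17A1, an enzyme of androgen synthesis, had 137 counts over all 44 libraries and was not tested.

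By gene list, the androgen-repressed genes rose under enzalutamide (camera, adjusted p = 0.00789; adjusted p = 0.212 with an estimated correlation), with 3 of 7 up and 1 down, the same counts as adjusted over the list alone. CAMK2N1, an inhibitor of CaM kinase II, rose by 0.81 ± 0.14 and OPRK1 by 0.79 ± 0.23 (lost without enzalutamide 1), and UGT2B10, a glucuronosyltransferase, fell by 0.91 ± 0.21 against the list's name. Without the filter on low counts the call of this list ended (adjusted p = 0.0673).

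Proliferation genes were lower under enzalutamide as a list (adjusted p = 3.38e-07; adjusted p = 0.617 with an estimated correlation). Of 27 members, 5 fell, 0 rose and 22 did not pass, and 7 fell when adjusted over the list alone. The 5 were the replication helicase genes MCM2 to MCM6, among them MCM6 at -0.31 ± 0.09 and MCM3 at -0.30 ± 0.08. Cholesterol and fatty acid synthesis genes were lower too (adjusted p = 0.000428; adjusted p = 0.636 with an estimated correlation), although only 2 of 21 members fell, SC5DL (-0.33 ± 0.09) among them, and the same 2 when adjusted over the list alone. Fibroblast markers were lower (adjusted p = 0.0460; adjusted p = 0.616 with an estimated correlation). Only 4 of the 12 listed members had enough counts to be tested, and COL1A2, DCN and LUM were among those left out. Of the 4, FBN1, which encodes fibrillin, fell by 1.07 ± 0.26, and 2 fell when adjusted over the list alone. The call of this list ended without the filter on low counts (adjusted p = 0.170). The host was a mouse, so these counts may come from tumor cells or from mouse reads, and no change in fibroblasts can be read from them.

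The calls of a pair of further lists depended on enzalutamide 4. ERG and ERG-associated genes were lower (adjusted p = 0.0262; adjusted p = 0.617 with an estimated correlation), with HLA-DMB at -1.63 ± 0.19 and CRISP3 at -0.44 ± 0.12 among 3 of 8 that fell, while PLA1A rose by 0.35 ± 0.10, with the same counts adjusted over the list alone. Without enzalutamide 4 the adjusted p was 0.0670, while HLA-DMB still had a median of 33.9 CPM in the 13 other libraries against 108 CPM under vehicle. Cytosolic ribosomal protein genes were lower (adjusted p = 0.0237; adjusted p = 0.641 with an estimated correlation) with 0 of 22 members past edgeR's test on their own or adjusted over the list alone, and their direction turned without enzalutamide 4 (adjusted p = 0.895).

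**Figure D2:**
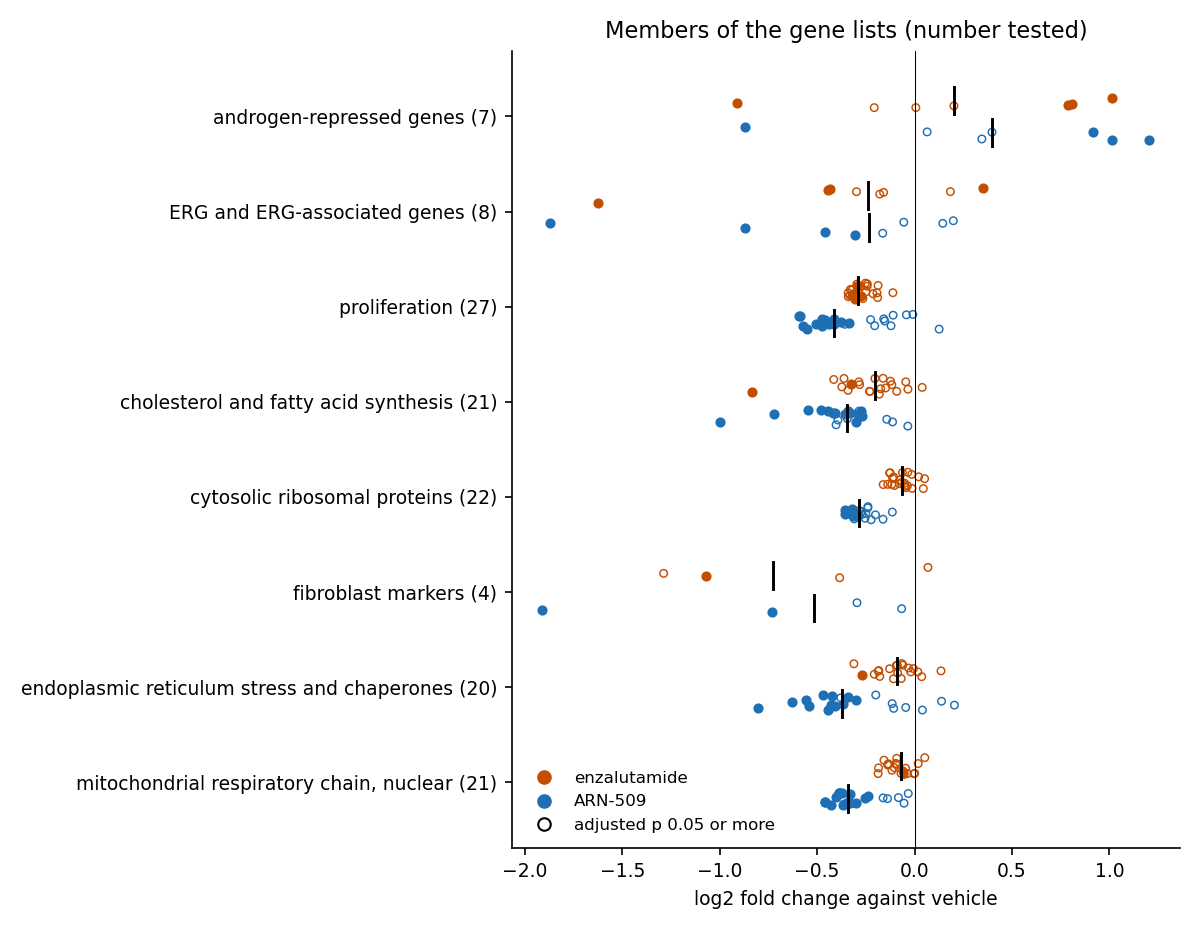
Log2 fold change against vehicle of each tested member of 8 gene lists, for enzalutamide and ARN-509; filled points passed an adjusted p of 0.05, open points did not, and black bars mark medians. Under ARN-509 the members of the respiratory chain, endoplasmic reticulum, lipid synthesis, ribosomal protein and proliferation lists lie mostly below 0, with medians from -0.28 to -0.41.

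ARN-509 against vehicle gave the second comparison. STEAP4 fell from 62.5 ± 41.3 to 4.54 ± 4.14 CPM (SD, n = 15 in each arm; log2 -3.75 ± 0.41, adjusted p = 6.25e-09), TRPM8 to 117 ± 49.1 CPM (log2 -2.03 ± 0.26, adjusted p = 1.99e-07) and FKBP5 by 0.60 ± 0.11 (adjusted p = 9.28e-05). KLK3 fell by 0.61 ± 0.21 (adjusted p = 0.0308), a call lost without vehicle 8 (adjusted p = 0.133). ERG fell by 0.46 ± 0.14 (adjusted p = 0.0113).

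Under ARN-509, 1620 genes rose and 1892 fell of 13517 (26.0%), and 92 and 102 of these changed at least 2-fold. With library totals as the only scaling, 2139 rose and 1097 fell. The genes that rose most were SLC7A14 (3.38 ± 0.26), NOV (3.21 ± 0.21), GRIA2 (3.04 ± 0.34), SAMD11, LOC100130417, the tetraspanin TSPAN7, the potassium channel KCNJ3, the calcium pump ATP2B2, FRAS1 and GNG2 (2.06 ± 0.23). Those that fell most were FAM189A2 (-4.31 ± 0.55), DPP4 (-4.09 ± 0.53), STEAP4, ST6GALNAC1 (-3.46 ± 0.31), KRT14 (-3.12 ± 0.32), LUZP2, TESC, CACNG4, PIGR and RHOJ (-2.40 ± 0.31). PIGR again lost its call without vehicle 12 (adjusted p = 0.0547). KLK2 (-0.25), NR3C1 (0.62), TMPRSS2 (0.03), UGT2B15 (0.35), UGT2B17 (0.40), AKR1C3 (0.12), MKI67 (-0.12) and TOP2A (0.13) did not pass the test. KLK2 and NR3C1 did pass when enzalutamide 4 was left out of the joint fit (adjusted p = 0.0106 and 0.0155).

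The androgen-repressed list rose under ARN-509 (adjusted p = 0.00405; adjusted p = 0.402 with an estimated correlation), with 3 of 7 up and 1 down, also when adjusted over the list alone. CAMK2N1 rose by 1.01 ± 0.14 and OPRK1 by 0.91 ± 0.22, and UGT2B10 fell by 0.87 ± 0.20. ERG and ERG-associated genes fell (adjusted p = 0.0251; adjusted p = 0.508 with an estimated correlation). Beside ERG, HLA-DMB (-1.87 ± 0.18) and ARHGDIB (-0.87 ± 0.13) were among 4 of 8 that fell, also when adjusted over the list alone.

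The proliferation, nuclear respiratory chain, lipid synthesis, endoplasmic reticulum and ribosomal protein lists were lower under ARN-509. Of 27 proliferation genes 16 fell and 0 rose, or 18 when adjusted over the list alone, with MCM5 at -0.57 ± 0.09 and MCM3 at -0.48 ± 0.08 (list adjusted p = 1.85e-06; adjusted p = 0.537 with an estimated correlation). Of 21 nuclear respiratory chain genes 16 fell and 0 rose, or 17 when adjusted over the list alone, with UQCRC1 of complex III at -0.46 ± 0.09 and SDHA of complex II at -0.37 ± 0.07 (list adjusted p = 6.88e-07; adjusted p = 0.508 with an estimated correlation). Of 21 cholesterol and fatty acid synthesis genes 14 fell and 0 rose, or 16 when adjusted over the list alone, with FDPS at -0.55 ± 0.11 and MVK at -0.48 ± 0.13 (list adjusted p = 1.84e-05; adjusted p = 0.508 with an estimated correlation). Of 20 endoplasmic reticulum stress and chaperone genes 12 fell and 0 rose, or 13 when adjusted over the list alone, with SDF2L1 at -0.81 ± 0.17 and the transcription factor gene CREB3L4 at -0.43 ± 0.07 (list adjusted p = 8.40e-05; adjusted p = 0.508 with an estimated correlation). Of 22 cytosolic ribosomal protein genes 6 fell and 0 rose, or 13 when adjusted over the list alone, with RPL11 at -0.35 ± 0.10 (list adjusted p = 0.00119; adjusted p = 0.716 with an estimated correlation). Beside these groups, the log2 fold changes under ARN-509 had a Spearman correlation of -0.41 with the GC content of the gene and 0.32 with transcript length. Those under enzalutamide against vehicle had the opposite signs, 0.17 with GC content and -0.17 with length. These values are across genes, which are not independent replicates.

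The responses to both drugs were then set side by side. Of the 13517 genes, 396 rose and 413 fell under each drug, against 73.5 and 89.7 for independent lists, and 0 moved past the threshold in opposite directions. Of the 110 genes that fell at least 2-fold under enzalutamide, 110 had a value of the same sign under ARN-509, and 73 fell at least 2-fold under each. Of the 86 that rose at least 2-fold, 77 had the same sign and 53 rose at least 2-fold under each. The log2 fold changes had a covariance of 0.0680 (r = 0.678) across genes. Comparisons with the same vehicle libraries share their chance values. In 20 simulations of unchanged arms against those libraries the covariance averaged 0.00287 (r = 0.225). By edgeR, 0 genes were called in each arm on average. The arms were drawn from the mean of those same libraries, so most of the shared chance value cancels and these values understate it. The difference of 0.0651 from the observed covariance is therefore no estimate of the covariance of the effects. The observed covariance had a jackknife SE of 0.0191. With odd-numbered vehicle libraries for enzalutamide and even-numbered ones for ARN-509 the covariance was 0.0569, and 0.0637 the other way round. No vehicle library served both drugs in these splits, so covariance of that size does not come from shared vehicle libraries.

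**Figure D3:**
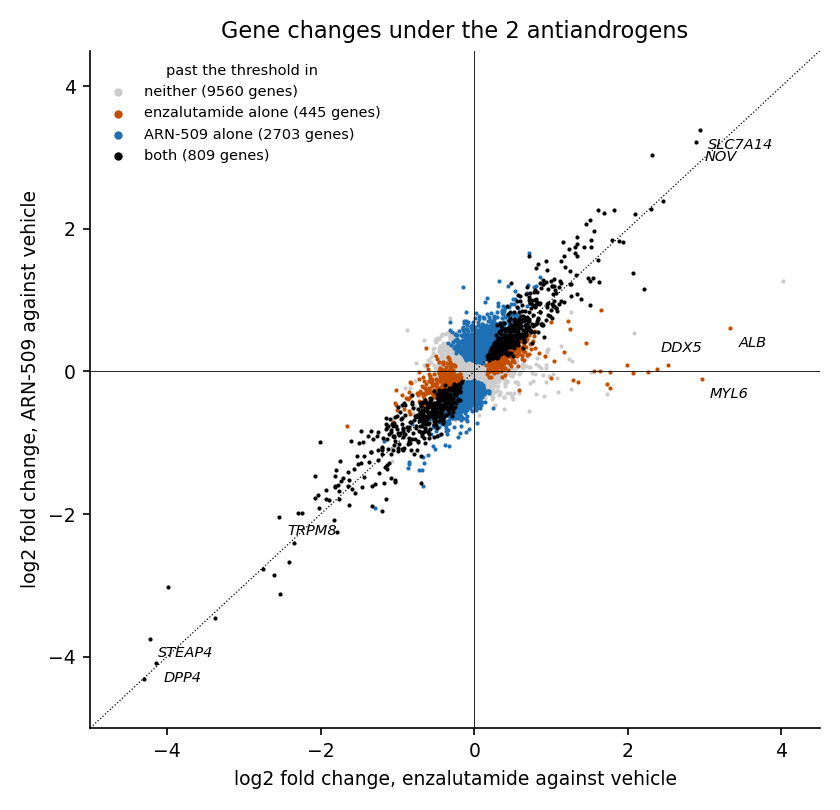
Log2 fold change against vehicle of 13517 genes under enzalutamide (x axis) and ARN-509 (y axis); colours mark genes past an adjusted p of 0.05 in both, 1 or neither comparison, and the dotted line is equality. The 809 genes past the threshold in both lie along the line, and MYL6 and DDX5, which rested on enzalutamide 4, lie far to the right near 0 on the y axis.

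The third comparison set the drugs against each other at the same dose and time. They share a diarylthiohydantoin core and differ in that ARN-509 (apalutamide) has a spiro-cyclobutane where enzalutamide has a dimethyl group, and a pyridine in place of one of its benzene rings. KLK3, KLK2 and FKBP5 did not pass the test between the drugs. For enzalutamide minus ARN-509 the log2 difference was 0.42 for KLK3 (95% interval -0.02 to 0.86), 0.19 for KLK2 (-0.04 to 0.41) and 0.14 for FKBP5 (-0.09 to 0.37). KLK2 passed without enzalutamide 4 (adjusted p = 0.0162).

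Across all genes, 1242 were higher and 1473 lower with enzalutamide than with ARN-509 (20.1% of those tested), with a median absolute log2 difference of 0.32 among them, and 27 differed at least 2-fold. Without enzalutamide 4, 11 differed at least 2-fold. The 95% interval of the difference lay within 2-fold for 13149 genes (97.3%). Of the 809 genes that moved together against vehicle, 50 differed between the drugs. The genes with the smallest p, each with an adjusted p of 0.00528, were lower with enzalutamide for BTAF1 (-0.74 ± 0.13), RASSF8 (-0.75 ± 0.14), BRWD1, SPOPL, JHDM1D, ZC2HC1A and SLC25A36 (-0.48 ± 0.09), and higher for AKT1S1, a subunit of mTORC1 (0.35 ± 0.07), SPSB1 (0.83 ± 0.16) and TLCD1. UGT2B15 (-0.14), UGT2B17 (-0.39), NR3C1 (-0.17), ERG (0.28), TMPRSS2 (0.19), AKR1C3 (0.15), MKI67 (-0.22) and TOP2A (-0.32) did not pass the test.

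Among the lists, nuclear respiratory chain genes were higher with enzalutamide than with ARN-509 (adjusted p = 0.000302; adjusted p = 0.953 with an estimated correlation). Of 21 members 9 were higher and 0 lower, or 15 when adjusted over the list alone, with UQCRC1 at 0.32 ± 0.09 and ATP5B, a subunit of ATP synthase, at 0.38 ± 0.12. Endoplasmic reticulum stress and chaperone genes were also higher (adjusted p = 0.0231; adjusted p = 0.953 with an estimated correlation), with 7 of 20 higher and 0 lower, also when adjusted over the list alone. SDF2L1 (0.74 ± 0.18), HYOU1 (0.51 ± 0.13) and CRELD2 (0.56 ± 0.16) were among them. With library totals as the only scaling that list lost its call (adjusted p = 0.0955), and 529 genes were higher and 1744 lower. Beside these groups, the log2 differences had a Spearman correlation of 0.58 with GC content and -0.49 with transcript length, across genes. The genes higher with enzalutamide had a median GC content of 57.2% and those lower 39.7%. Once each library's trend with GC content and length was removed, 439 genes differed, 289 higher and 150 lower. The count also fell to 1694 without enzalutamide 9 and to 1794 without ARN-509 6.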

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

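For enzalutamide against vehicle, limma voom with quality weights called 2559 genes in place of 1254, and 196 of the 1254 changed at least 2-fold. Leaving out 1 library gave 1031 (vehicle 9) to 1515 (vehicle 11) in 29 fits. Of 1266 values of named genes under other settings, 1190 kept their call. A change of sign was counted as reversed only where either fit passed, which held for 3. These were all DDX5, at -0.000402 by DESeq2, -0.00033 by limma and -0.012 without enzalutamide 4. Gene lists numbered 11 by library totals, 2 by fry and 0 with an estimated correlation, in place of 7. The ribosomal protein list turned direction without enzalutamide 4 (adjusted p = 0.895) and with the GC and length trend removed (adjusted p = 0.150), and the cause was not tested.

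For ARN-509 against vehicle, 194 of the 3512 genes changed at least 2-fold. With the GC and length trend removed, 2765 of the 12023 genes with a GC value passed. These held 2052 of the 3512 (58.4%). Only 90.1% of the 3512 had a GC value and could be tested again. Leaving out 1 library gave 2686 (vehicle 8) to 4409 (vehicle 10) in 30 fits. Of 1269 values, 1202 kept their call and 1 reversed, HSD17B4 at -0.00126 with the GC and length trend removed. With an estimated correlation 0 lists passed in place of 9.

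For enzalutamide against ARN-509, limma with quality weights called 5779 genes in place of 2715. Of the 2715, 27 differed at least 2-fold. With the GC and length trend removed 439 genes differed, 38 of them at least 2-fold, and 272 of the 439 were among the 2715. Without enzalutamide 4 the same removal gave 724 genes, 7 of them at least 2-fold. Leaving out 1 library gave 1694 (enzalutamide 9) to 3623 (enzalutamide 4) in 29 fits, and 1794 for ARN-509 6. Of 1187 values, 1089 kept their call and 0 reversed. Lists numbered 1 by library totals, 0 with an estimated correlation and 0 by fry, in place of 2.

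Replicate numbers in the titles share only a number. Tumors of the same number had a mean r of 0.0234, 0.0605 and 0.00397 in their deviations from the arm means. With the replicate number as a block 1012, 3250 and 1993 genes passed.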

Other observations

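Some groups changed in single members without a change of the whole list. Among genes that glucocorticoids induce, SCNN1A, a sodium channel subunit, rose by 2.21 ± 0.44 under enzalutamide and KLF9 by 1.48 ± 0.39, whereas FKBP5 fell. Of 12 members 2 rose and 1 fell (list adjusted p = 0.186; 3 and 2 over the list alone). Under ARN-509, KLF9 rose by 1.32 ± 0.37 and TSC22D3 by 0.52 ± 0.12 among 3 that rose and 2 that fell (list adjusted p = 0.597; 3 and 3 over the list alone). In steroid synthesis, HSD17B6 fell by 0.76 ± 0.11 under each drug (list adjusted p = 0.652 and 0.674), and HSD17B4 (0.30 ± 0.07) and SRD5A3 (0.31 ± 0.08) rose under enzalutamide. HSD17B4 also rose past the threshold under ARN-509, but not with the GC and length trend removed (-0.00126, adjusted p = 0.997). Among 4 basal epithelial genes KRT14 fell under each drug while the integrin ITGB4 rose, by 0.65 ± 0.14 with enzalutamide and 0.50 ± 0.14 with ARN-509 (list adjusted p = 0.321 and 0.870). Among 11 luminal genes CD24 rose by 0.28 ± 0.08 and 0.42 ± 0.08, and KRT18 fell by 0.32 ± 0.08 under ARN-509 and did not pass under enzalutamide (-0.17) or between the drugs (0.15) (list adjusted p = 0.186 and 0.333).

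Neuroendocrine genes did not pass as a list (adjusted p = 0.0960 and 0.260), although SCG2 rose by 1.22 ± 0.34 under enzalutamide (lost without enzalutamide 5, adjusted p = 0.0593) and the adhesion molecule NCAM1 by 0.77 ± 0.18 under ARN-509. Of 11 interferon response genes IRF7 (-0.44 ± 0.13) and OAS3 (-0.45 ± 0.14) were among 3 that fell under ARN-509. DDX60 fell under enzalutamide (-0.92 ± 0.26, adjusted p = 0.0527 without vehicle 12). The list adjusted p was 0.0553 under enzalutamide and 0.260 under ARN-509. Fibroblast markers did not pass under ARN-509 (adjusted p = 0.260), where PDGFRA fell by 1.91 ± 0.50. Under enzalutamide the respiratory chain list (adjusted p = 0.0635), the endoplasmic reticulum list (0.0787) and hypoxia and glycolysis genes (0.0553) did not pass; for hypoxia the value under ARN-509 was 0.629. Mesenchymal transition, immediate early, endothelial, and muscle and fat genes passed under neither drug, with adjusted p from 0.584 to 0.997.

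The muscle gene list was chosen after enzalutamide 4 had been seen to stand apart. Host muscle in place of tumor might explain this library, since 14 of 16 muscle and connective tissue genes lay above their highest CPM in the other 43 libraries. ACTC1 reached 1772 CPM against at most 14.7 elsewhere, MYH4 1685 against 7.97, and KLK2 724 CPM against at least 3551. COL1A2 and COL3A1 had 0 counts, which at this depth allows up to 46.0 CPM, so tissue of the host cannot be told from another cause. Low depth alone does not explain it, since the 13 other enzalutamide libraries thinned to 80142 counts kept an r of at least 0.836, against 0.577 for this library.

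The removal of the GC and length trend, the thinning and the fits without enzalutamide 4 were chosen after the differences between the drugs had been seen. RNA quality or library preparation differing between the arms could account for most of the differences between enzalutamide and ARN-509, since 439 genes differed once the trend was removed, in place of 2715. Across the 2474 earlier genes with a GC value the median log2 difference in the original direction went from 0.32 to 0.13, and 272 still passed in that direction. The respiratory chain and endoplasmic reticulum lists stayed higher with enzalutamide after the removal at the preset correlation (adjusted p = 4.44e-06 and 0.00669), although only 1 member of each still passed on its own. An estimated correlation was not tried after the removal, and before it each list had an adjusted p = 0.953 with an estimated correlation. Removal would also take away a biological difference that runs along GC content, and single genes such as SDF2L1 and UQCRC1 cannot be assigned to either. Unequal depth does not explain them, since 2963 genes differed after thinning (3623 before, without enzalutamide 4). Chance in how tumors fell into arms is unlikely but not excluded. Of 100 splits of these libraries only the real 1 reached 2715, with at most 0 genes in any other. Ribosomal protein genes did not pass between the drugs in the fit of all libraries (adjusted p = 0.409; adjusted p = 0.953 with an estimated correlation). Without enzalutamide 4 they passed at the preset correlation (adjusted p = 7.12e-08), and an estimated correlation was not tried there.

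The same removal was applied after the lower respiratory chain, endoplasmic reticulum and lipid synthesis genes of ARN-509 tumors had been seen. The trend alone does not account for them, since 32 of the 42 members of these lists that fell stayed lower and past the threshold. Among the 32 were UQCRC1, SDF2L1 and FDPS. Only 40 of the 42 had a GC value and could be tested again. For ARN-509 against vehicle 1 of 100 splits, the real one, reached 3512 genes, and the highest other had 46. Chance in how tumors fell into arms is thus unlikely there, but 100 splits cannot exclude it. For enzalutamide against vehicle 2 of 100 reached 1254, with 2495 in the highest other split and 0 in 93 of 99. Fewer than 5 of 100 was the limit for calling chance unlikely, and which samples the highest other split grouped was not examined. No biological explanation was tested.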
